A study of Homo sapiens with 8 samples.

How the data were processed

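Gene expression was measured on 8 Illumina HumanRef-8 v2.0 arrays, 4 of outer and 4 of inner cells of MCF10A-5E acini, grouped by the titles of the samples. Per the labels, each sample held about 50 microdissected cells, whose RNA was amplified by poly(A) PCR. The series' design text speaks of RNA amplified in quadruplicate, and the labels do not tie samples to separate cultures or acini. The p-values therefore measure only the spread between these samples, which may be technical, and may be too small.

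The authors deposited the mean bead intensity of each probe, not background-subtracted and not normalized, per the file headers and the values. The deposited detection p-value of each probe and array is, for 92.5% of probes, a whole multiple of one step on all arrays, as a rank among a fixed number of controls would be. The authors' scaled values are a ratio of each intensity to the mean intensity of its array, as recomputed here from the deposited columns. The deposited inner over outer ratio is that of the medians of 4 arrays. The scanning software and its version are not given in the sources used here. All 3 deposited tables hold the same arrays, and the 2 tables with raw intensities were equal.

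Intensities were processed with neqc of limma 3.58.1 in R 4.3.3: normexp background correction from the detection p, an offset of 16, quantile normalization and log2. The 1 probe without beads on an array was left out. Probes with a detection p below 0.01 on at least 4 arrays were tested. Outer minus inner was fitted with lmFit and eBayes, with group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A second count required an absolute log2 difference of at least 1. Gene lists, 38 in all, were tested with camera at a preset correlation of 0.01 on the probe with the highest mean per gene, where at least 5 genes were measured, beside camera with an estimated correlation and fry. Lists adjusted alone are given beside adjustment over all probes. Array measures were compared by an exact permutation test.

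The background parameters deserve care. Of the 20589 probes 1535 have a detection p off the regular steps, and 197 of the 273 such probes with a mean intensity above 300 missed the detection filter, against 37 of 4277 among the others. With all probes, neqc inferred a background mean of 96.5 to 126 and an SD of 262 to 391 per array. The probes on the steps alone gave 31.1 to 38.5 and 6.24 to 12.4. The larger estimate draws dim probes together, so that their fold differences, and the spread between their replicates, are understated. The neqc fit is kept as the main result because the fit, the gene lists and the rule for naming genes were fixed before the data were examined. The fit on the regular probes was added after the neqc results had been seen and was for a time taken as the main one. The results of both were known when neqc was kept. The probes it called, and the mean of each list called with neqc, are given beside those of neqc.

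Gene names come from the deposited table. Symbols were current for 15331 probes, updated through a table of RefSeq gene names (GRCh38.p14) for 3597 and kept for 1661, and 25 that a spreadsheet had turned into dates were recovered from the probe's definition where possible. No coordinates were used.

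Genes were named by rule. It takes up to 12 genes per direction with the largest difference among those past the threshold with groups that do not overlap, filled up to 5 with the smallest p where fewer pass. It adds up to 4 members with the smallest p of each list past its threshold, and a set of fixed genes with roles in this tissue. Genes outside it were named after their values were seen: FLJ38482, GADD45A, PEX13, MUC1, ELF3, NDUFB3, NDUFA8, CDC25C, HMMR, CDCA8, ABCC3, GCLM, NQO1, TXN and PRDX1, and those in the closing paragraphs. Results for some genes that the rule or an alternative would name are not reported here.

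The fit was tested on simulated arrays with the means and spreads of the 6698 probes of this comparison. Of 50 probes each changed 2-fold, 4-fold, 8-fold and 16-fold, 52%, 76%, 90% and 94% were called, with 14 false calls, and a simulation without changes gave 0 calls. A planted list of 40 genes shifted by 0.5 was called, and 0 of 34 lists without a shift were. The simulated probes varied independently of each other, so this does not show how often lists of correlated genes are falsely called. The changes were added to values already processed with neqc. The shares called therefore leave out how far neqc shrinks a true change of a dim probe. Many changed probes at once also ease the adjusted threshold, so the shares may be too high for these data.

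Alternatives were the authors' scaled values, other background corrections, other scalings, other detection filters, other variance models, the replicate number as a block, averaged probes and leaving out each array. The BeadChip as a block was not run, because no column names a chip. Plots were drawn with matplotlib 3.10.9.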

Results

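MCF10A is an immortalised, non-tumorigenic human breast epithelial cell line, and MCF10A-5E is the clone used here. Grown on reconstituted basement membrane, its cells form hollowing spheres called acini, in which an outer layer touches the extracellular matrix and inner cells do not. At day 6 about 50 outer cells or about 50 inner cells per sample were cut from 8 µm sections by laser microdissection, and their RNA was amplified by poly(A) PCR and hybridised to Illumina HumanRef-8 BeadChips. There were 4 arrays of outer cells and 4 arrays of inner cells, with 20589 probes each. Between 6429 and 7000 probes per array had a detection p below 0.01, and the mean intensity of an array lay between 344.4 and 533.0. Detected probes numbered 6581 ± 131 on outer arrays and 6698 ± 202 on inner arrays (SD, n = 4 each), a difference of -116.5 that did not exceed the spread between arrays (exact two-sided permutation test, p = 0.371, where the smallest possible p is 0.0286). Correlations across probes were 0.873 to 0.883 within a group and 0.860 to 0.875 between groups, with probes not being independent replicates. The number of arrays limits the precision of every value given here.

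The comparison asks how gene expression differs between matrix-attached and inner cells of such acini. KNTC1 (probe ILMN_25890), a kinetochore protein of the spindle checkpoint, was higher in outer cells, with a log2 intensity of 10.15 ± 0.30 against 7.71 ± 0.32 in inner cells (SD, n = 4 each). Its log2 difference was 2.45 with a standard error of 0.21, a 5.45-fold difference (limma, adjusted p = 0.0413), and it was higher in each outer array than in any inner array. KNTC1 was detected on 4 outer and 2 inner arrays, so that its difference is taken partly against background, and it ranged from 2.35 to 4.07 over the other settings. Its small inner SD also rests on the neqc background estimate, which draws dim values together. KNTC1 was the 1 probe among 6698, for 6572 genes, that passed the adjusted threshold, and it also passed the 2-fold threshold. Its call ended in 14 of the 20 other settings that tested it, with adjusted p from 0.00800 to 0.347 over these settings. Of the 8 fits that leave out 1 array, the one without inner replicate 3 kept KNTC1 and also called ZNF616, among 3 probes. Without inner replicate 4 the 1 probe was for PEX13, and without inner replicate 1 or 2 or any 1 outer replicate 0 probes passed. The authors' scaled values gave 0 higher and 3 lower probes, for ZNF616, FABP4 and FLJ38482, against 1 higher and 0 lower.

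No probe lower in outer cells passed the threshold. The 5 with the smallest p in that direction were MAOA, BTG1, SOD2, FABP4 and ZNF616. MAOA, a mitochondrial monoamine oxidase, differed by -0.56 on the log2 scale (adjusted p = 0.152), and passed where eBayes was run with a trend and robust (adjusted p = 0.0259, with a range over its alternatives of 0.0259 to 0.516). BTG1, an antiproliferative gene, differed by -0.91, and SOD2, the mitochondrial superoxide dismutase, by -1.08 (both adjusted p = 0.152). FABP4, a fatty acid binding protein detected on 2 outer arrays, differed by -1.01 (adjusted p = 0.180), and by -3.53 to -0.88 over the other settings. ZNF616, a zinc finger gene, was not detected on any outer array and was at least 2.10-fold lower there (adjusted p = 0.184). This bound sets the mean of the inner arrays against the lowest detected signal of each outer array, or the probe's own signal where that was higher. In the other direction the next smallest p belonged to CDC23, a subunit of the anaphase-promoting complex, at 1.30, and to PLAGL1, a zinc finger transcription factor, at 1.14. PLAGL1 was detected on 1 inner array, so that its difference is taken mostly against background, and it ranged from 1.07 to 3.96 over the other settings. SH2D2A, an adaptor protein, followed at 1.90. Adjusted p for these 3 was 0.184, past the threshold for none.

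The background estimate decides which single genes pass. Taking it from the 19054 probes whose detection p lies on a regular grid, a setting added after the first results were seen, gave 4 probes. ZNF616 was then at least 18.1-fold lower (adjusted p = 0.00473), FABP4 lower by a log2 difference of -3.53 (adjusted p = 0.00815) and FLJ38482, an uncharacterised transcript not detected on any outer array, at least 9.98-fold lower (adjusted p = 0.0196). GADD45A, a stress-response gene not detected on any inner array, was at least 6.23-fold higher in outer cells (adjusted p = 0.0196). These bounds rest on the on-grid background. With neqc the log2 difference was 0.29 for GADD45A (adjusted p = 0.341) and -0.55 for FLJ38482 (adjusted p = 0.458). With the on-grid background KNTC1 had a log2 difference of 4.07 with adjusted p = 0.347. The SD of its inner arrays was 2.17, against 0.32 with neqc.

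**Figure D1:**
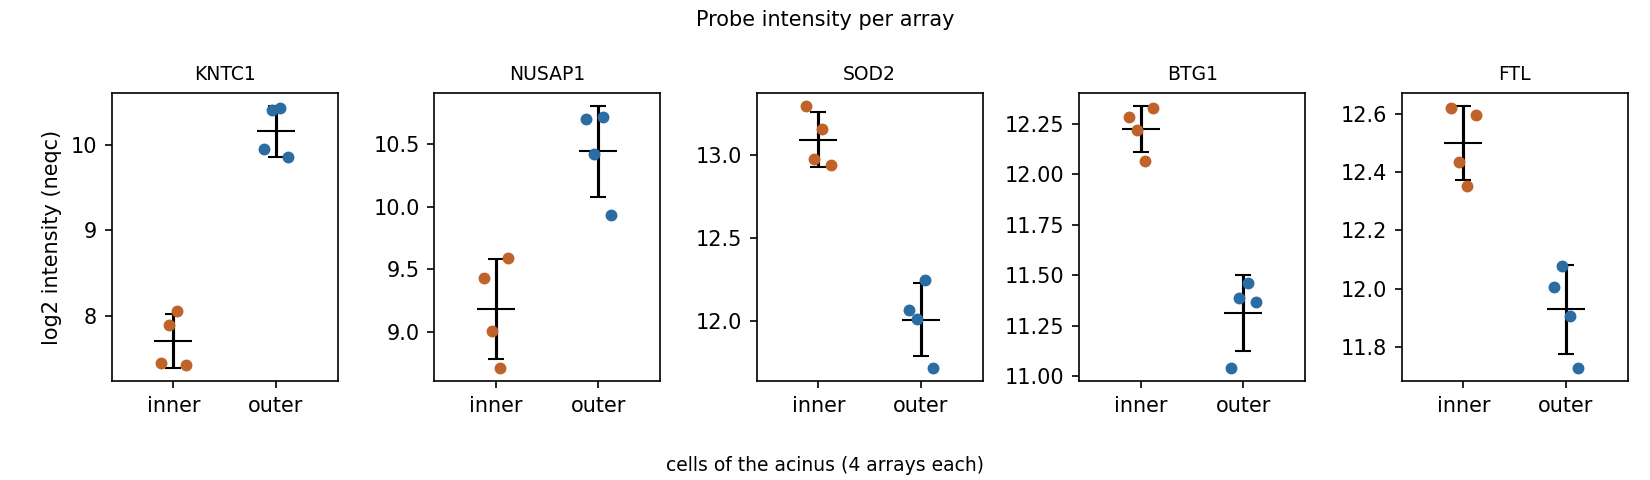
Log2 intensity after neqc of 5 genes on the 4 inner and 4 outer arrays, with 1 point per array, a bar at the mean and error bars of 1 SD. All 4 values of one group lie apart from all 4 of the other in each panel, but of these genes only KNTC1 passed the adjusted threshold (0.0413).

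At an unadjusted p below 0.05 there were 540 probes, 257 higher and 283 lower in outer cells, where chance gives 334.9. The 4 values of one group lay wholly above those of the other for 352 probes, 5.26% of those tested, where chance gives 2.86%.

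Genes of the mitosis list, which hold the spindle, kinetochore and mitotic kinase genes, were higher in outer cells as a group. Of 39 measured members 36 were higher and 3 lower, with a median log2 difference of 0.38 (camera, adjusted p = 6.6e-06 over 34 lists), and this call held with an estimated correlation (adjusted p = 0.0297). No member passed the threshold alone, over all probes or adjusted over the list alone, and 5 higher and 1 lower had an unadjusted p below 0.05. NUSAP1, a spindle-associated protein, had a log2 difference of 1.26 with a standard error of 0.25, and KIF23, a kinesin of cytokinesis, one of 1.06 (0.88 to 1.95 over the other settings). BUB1B, a checkpoint kinase, differed by 0.98 and CENPA, the centromeric histone, by 0.97. The 3 lower members were CDC25C at -1.35, larger in size than any of these 4, HMMR at -0.71 and CDCA8 at -0.11. The mean log2 difference of the list was 0.41, with 0.58 with the on-grid background and 0.35 to 0.58 over all other settings. The mean of the list per array was 9.84 ± 0.04 in outer and 9.43 ± 0.12 in inner cells (SD, n = 4 each).

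Genes of the S phase and replication list were also higher in outer cells, 18 of 21 measured, with a median log2 difference of 0.45 (camera, adjusted p = 0.00351). With an estimated correlation the call was lost (adjusted p = 0.152), and with the 17 members measured on all 8 arrays adjusted p was 0.0520. No member passed the threshold, over all probes or adjusted over the list alone. The mean log2 difference of the list was 0.37, with 0.69 with the on-grid background and 0.23 to 0.69 over all other settings. CDC45, part of the replicative helicase complex, had a log2 difference of 0.64 (0.56 to 2.38 over the other settings), and MCM7, a subunit of that helicase, one of 0.39. POLE2, a polymerase subunit, gave 0.26. POLE2 and MCM7 were each detected on 1 inner array. For MCM7 this does not show a low signal, as its mean log2 intensity in inner cells was 10.25. The lowest detected signal of inner replicate 1 was 7.46. The difference of POLE2, whose inner values lie near background, ranged from 0.19 to 2.27. PRIM1, the primase, lay in the other direction at -1.05 (-1.91 to -0.81 over the other settings).

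**Figure D2:**
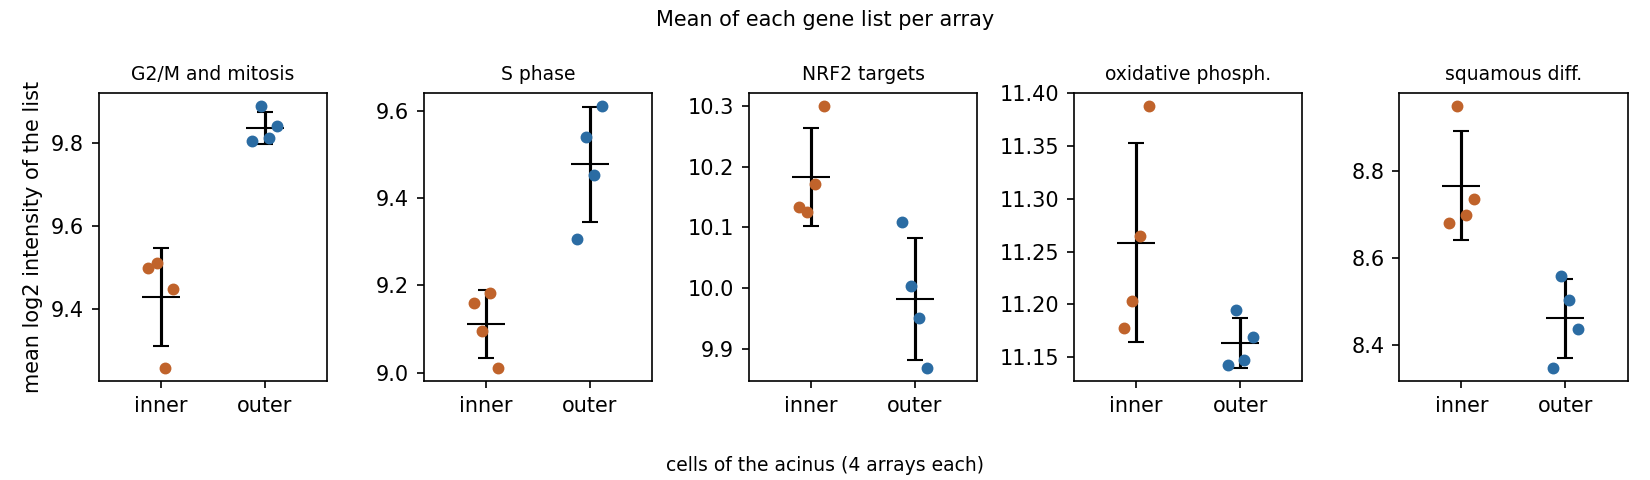
Mean log2 intensity of the measured members of 5 gene lists on each array, with 1 point per array, a bar at the mean and error bars of 1 SD. For mitosis genes the outer arrays average 9.84 and the inner arrays 9.43. Each vertical axis has its own range.

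Targets of NRF2, a regulator of antioxidant and detoxifying enzymes, were lower in outer cells, 14 of 19 measured, with a median log2 difference of -0.16 (camera, adjusted p = 0.0123). With an estimated correlation, -0.025 against the preset 0.01, the call was lost (adjusted p = 0.152). Adjusted over the list alone, 2 members passed, against 0 over all probes: FTL, the ferritin light chain, at -0.57, and AKR1C3, an aldo-keto reductase, at -0.87. AKR1B10, detected on 2 outer arrays, differed by -0.40 (-2.61 to -0.34 over the other settings) and TALDO1, of the pentose phosphate pathway, by -0.20. The 5 higher members were ABCC3 at 0.53, GCLM at 0.19, NQO1 and TXN at 0.10 and PRDX1 at 0.01, none with an unadjusted p below 0.05. The mean log2 difference of the list was -0.20, with -0.45 with the on-grid background and -0.45 to -0.16 over all other settings. Without inner replicate 4 adjusted p was 0.0694, and with median scaling 0.0590.

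Squamous differentiation genes were lower in outer cells, 11 of 13 measured, with a median log2 difference of -0.23 (camera, adjusted p = 0.0339). With an estimated correlation, -0.015 against the preset 0.01, the call was lost (adjusted p = 0.211). S100A8, a calcium-binding protein of stressed epithelium, at -0.60, was the 1 member that passed adjusted over the list alone, against 0 over all probes. SPRR1B, a cornified envelope precursor, differed by -0.41, KRT10 by -0.94 and PPL, periplakin, by -1.12. PPL was at -0.62 without inner replicate 4 and at -1.74 without inner replicate 2. The mean log2 difference of the list was -0.30, with -0.47 with the on-grid background and -0.08 with no filter on detection, the ends of its range. Adjusted p was 0.148 without inner replicate 2, 0.0719 without outer replicate 1, 0.0590 with median scaling, 0.0556 with a saddle-point background and an offset of 50, and 0.333 with no filter on detection.

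Oxidative phosphorylation genes were lower in outer cells by little, 32 of 45 measured, with a median log2 difference of -0.11 (camera, adjusted p = 0.00613). With an estimated correlation the call was lost (adjusted p = 0.249). No member passed, over all probes or adjusted over the list alone, and 2 higher and 5 lower had an unadjusted p below 0.05. ATP5PD and ATP5ME, subunits of ATP synthase, differed by -0.39 and -0.60, and COX7B and COX4I1, subunits of cytochrome c oxidase, by -0.27 and -0.31. A second probe of ATP5PD gave -0.19. The largest differences lay in the other direction, with NDUFB3 at 0.96 and NDUFA8 at 0.86, subunits of complex I (adjusted p = 0.521 and 0.491). Cytosolic ribosomal protein genes, a sign of RNA quality, were lower in outer cells for 44 of 71, with adjusted p = 0.0568, and passed in 7 of 23 other settings (0.00797 to 0.486), among them without inner replicate 2 (0.0370), inner replicate 3 (0.0274) or outer replicate 2 (0.0124). The oxidative phosphorylation call was lost with each of 3 other background treatments (adjusted p from 0.0589 to 0.0747), with the authors' scaled values (0.0794), with median scaling (0.108), with fry (0.0702) and without inner replicate 4 (0.0788), where the mean log2 difference was -0.05 against -0.10. With the on-grid background it was -0.13.

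No list of markers of cell position passed the threshold. Basal and myoepithelial markers were higher in outer cells for 8 and lower for 9 of 17 (camera, adjusted p = 0.530). KRT5 and KRT14, basal keratins, differed by 0.16 and -0.19, and TP63, their regulator, by -0.28. Leaving out 1 array moved KRT5 to 0.10 (without inner replicate 3), KRT14 to -0.10 (without inner replicate 2) and TP63 to between -0.46 (without inner replicate 2) and -0.15 (without inner replicate 1 or 4), with -0.17 without outer replicate 4. Luminal markers were lower for 5 of 7 (adjusted p = 0.0900), with KRT8 at -0.11 (-0.55 to -0.08 over the other settings), MUC1, an apical mucin, at -1.60 and ELF3, an epithelial transcription factor, at -0.91. This list passed with the authors' scaled values (0.0440), with no filter on detection (0.0476) and with fry (0.0499), in a range of 0.0440 to 0.307 over 23 other settings. Adjusted over the list alone 1 member, MUC1, passed, against 0 over all probes. Integrins and hemidesmosome genes split 6 to 6 (adjusted p = 0.781), with ITGB4 at 0.17 (0.11 to 0.40 over the other settings) and ITGB1 at -0.00, a direction that flips in 5 settings. LAMA3, a laminin chain, differed by 0.51 (adjusted p = 0.416), in a basement membrane list with adjusted p = 0.964. The pro-apoptotic list had 3 higher and 5 lower members (adjusted p = 0.102). JUND differed by -0.82 and TGFBR3 by -0.42, with adjusted p = 0.461 and 0.894, and TGFBR3 was detected on 1 outer and 4 inner arrays. Without that outer array, outer replicate 4, TGFBR3 was at -0.95, without outer replicate 1, 2 or 3 or inner replicate 1 at -0.27 to -0.24, and over all other settings at -2.93 to -0.24. MKI67, a proliferation marker, differed by 0.44 and CCND1 by 0.35 (adjusted p = 0.812 and 0.742), with MKI67 at 0.10 without outer replicate 2 and CCND1 at 0.16 without outer replicate 4. Over all other settings MKI67 ranged from 0.10 to 1.41 and CCND1 from 0.16 to 0.86. KRT18, KRT19, ITGA6, LAMB3, BCL2L11, BMF and CDKN1B were detected on too few arrays to be tested. KRT19, ITGA6, BCL2L11 and BMF were detected on 0 arrays, LAMB3 on 1 outer array, CDKN1B on 1 outer and 1 inner array, and KRT18 was detected on 2 inner arrays. As with MCM7, a missed detection does not by itself show a low signal, so these counts do not show that the genes are silent.

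Among markers of other cell types, 4 of 12 fibroblast genes, 2 of 12 endothelial genes and 2 of 17 leukocyte genes were measured, too few to test. Their median log2 differences were 0.16, -0.06 and -0.13. Housekeeping genes gave adjusted p = 0.985.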

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

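The split counts for S phase, squamous differentiation and the on-grid background, and the tests of NRF2 targets with cyclic loess and of the trend with intensity, were chosen after the results were seen. In 100 groups of 4 values, 7 had 1 value far from the other 3, where chance gives about 1 in 20.

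The number of detected probes was 7000 on inner replicate 3, against 6571 to 6615 on the other inner arrays. PLAGL1 was at a log2 intensity of 7.88 on inner replicate 3, with the others at 7.43 to 7.44. TGFBR3 was at 9.55 on outer replicate 4, with the others at 7.43 to 7.47. POLE2 was at 7.63 and AKR1C3 at 11.52 on inner replicate 2, with the others at 7.44 to 7.46 and 11.30 to 11.34. ITGB4 was at 7.83 on outer replicate 1, with the others at 8.13 to 8.14. ZNF616 was at 7.47 on outer replicate 1, with the others at 7.43.

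The 1 probe past the adjusted threshold cannot be set apart from chance: 9 of the 35 splits of the 8 arrays gave at least as many, up to 3, and 7 did so with the 2-fold threshold, up to 3. With the background from probes on the regular grid, 7 of 35 splits gave at least the 4 probes of the real one, up to 6. At an unadjusted p below 0.05 the 540 probes were matched by no other split, so 1 of 35 gave as many, and the highest other was 374, while for the number of gene lists, 5 here, 1 of 35 gave as many, and the highest other was 3. With this filter and the preset correlation, a chance division of the arrays is thus unlikely for the unadjusted count and the number of lists. This is at the smallest share that 35 splits allow, and it does not hold for the number of single genes. The splits were not run with no filter, where 1031 probes stand against 1029 by chance, or with the settings that leave 1 or 2 lists.

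Over an exact enumeration of the 35 splits, 1, the real one, gave a camera p as small as 2.0e-07 for mitosis genes, with the smallest other at 0.000113. For the S phase list 1 split, the real one, gave a camera p as small as 0.000206, with the smallest other at 0.000947. A chance division of the arrays is thus unlikely for each, at the smallest share that 35 splits allow. Several lists were tested this way, so chance is not excluded. The mitosis median lay at percentile 100 of random lists matched on mean intensity, which argues against a bias with intensity, and its mean difference was at its lowest 0.349, without inner replicate 3, when 1 array was left out, which argues against a single array. What stays open is that the arrays of a group may be repeat amplifications of 1 pool of cells, so that the few cells caught in each pool could give the same pattern, which the labels do not settle. A difference between the positions in the acinus also stays open and was not tested apart from this.

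Over the same exact enumeration 1 of 35 splits, the real one, gave a camera p as small as 0.00145 for NRF2 targets, with the smallest other at 0.0114, and 1 of 35 one as small as 0.00498 for squamous genes, with the smallest other at 0.0264. The NRF2 median lay at percentile 2.29 of matched lists, near the bound of 2.5. With cyclic loess, which removes trends with intensity, the mean log2 difference was -0.20 as without it (camera, adjusted p = 0.00517). The trend of all differences with intensity lay between -0.01 and 0.01. Quantile normalization had already made such trends small, so these checks were unlikely to find one. They show only that little trend is left in the values tested. Median scaling, which shifts each array as a whole, also gave -0.20, but lost the call (camera, adjusted p = 0.0590). For oxidative phosphorylation 2 of 35 splits gave a camera p as small as 0.000541, with the smallest other at 0.000141 (exact enumeration), so chance is not excluded, although its median at percentile 0.55 argues against a bias with intensity. A pool of few cells and the position in the acinus both stay open, and neither was tested apart from the other.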

How the results depend on the processing

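The on-grid background was chosen after seeing the data, and the other settings before. Probes past adjusted p, 1 here, numbered 4 with the on-grid background, 3 with the authors' scaled values, 2 with a saddle-point background and an offset of 50, 3 without background correction, and 0 with no filter on detection, with detection p below 0.05 on 4 arrays or with detection on all 8. The same counts held with the 2-fold threshold, where eBayes with trend and robust gave 0 as well. Leaving out 1 array gave 0 to 3 probes by either count: 3 without inner replicate 3, 1 without inner replicate 4 and 0 without each of the others, with 493 to 553 at an unadjusted p below 0.05. With no filter 1031 of 20588 probes (5.01%) had an unadjusted p below 0.05, where chance gives 1029, so over all probes there was no excess, against 8.06% of the 6698 tested. With the other filters there were 598, where chance gives 391.7, and 378, where chance gives 209. Gene lists past the threshold, 5 here, numbered 3 with the saddle-point background and offset of 50, 2 with median scaling and 1 with an estimated correlation, and 3 to 6 when 1 array was left out, with 3 without inner replicate 4. The cause was not tested. The replicate block gave 1 probe, 1 at 2-fold and 5 lists. Same-numbered arrays correlated by 0.0140, 0.0275, 0.0127 and -0.0393 in their deviations, which shows no clear pairing by number. These values cannot exclude a pairing, because even 2 probes of a gene correlated by only 0.148 in such deviations. The difference in detected probes ranged from -172.4 to -15.8 when 1 array was left out and was -242.3 at detection p below 0.05. Of 41 named genes 1, ITGB1, changed sign in some setting, and no called value reversed. The mitosis list held in all 23 settings, S phase in 21, NRF2 in 20, squamous in 17 and oxidative phosphorylation in 15. YAP targets are measured on too few genes when all 8 arrays must detect them, so no value is given. The BeadChip as a block was not run. Signal close to background limits the values of dim probes.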

Other observations

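Some lists outside the 5 called ones held members that passed when adjusted over the list alone, although none passed over all probes. These genes were chosen after their values were seen. In the focal adhesion list FERMT1 and CAV1, a kindlin and a caveolin, differed by 1.25 and 0.32, and FERMT2, another kindlin, by -0.51, with 9 of 13 members higher in outer cells (camera, adjusted p = 0.423). DKK1, a secreted Wnt inhibitor, differed by 1.11, and ETV4 and PHLDA1, targets of ERK signalling, by 2.09 and 0.47. NFKBIA, an NF-kB inhibitor, differed by -1.03, HSPB1, a small heat shock protein, by -0.56, and PFKM, of glycolysis, by -0.71. In the p53 list BTG2 differed by -0.63, while GADD45A, detected on no inner array, was at least 1.20-fold higher in outer cells. GADD45A and SOD2, at -1.08, were also the members of the FOXO list that passed, in opposite directions. YAP targets were higher for 7 of 10 (adjusted p = 0.0874). They passed without background correction (0.0449), without outer replicate 3 (0.0323) and with the on-grid background, chosen after seeing the data (0.0469), in a range of 0.0323 to 0.413 over the settings. FOXO targets were lower for 10 of 15 (adjusted p = 0.0793), and passed with detection on all 8 arrays (0.0263) and without inner replicate 2 (0.0370), in a range of 0.0263 to 0.249. Lysosome genes, lower for 17 of 26 (adjusted p = 0.0874), passed with fry (0.0264, in a range up to 0.249), and EGF receptor and ERK targets, higher for 10 of 19 (adjusted p = 0.153), with no filter on detection (0.0161, in a range up to 0.326).

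A hypothesis was that genes induced by glucocorticoids, which the medium contains, are lower in outer cells. It came from the 40 smallest p values, where MAOA, BTG1, NFKBIA, TSC22D3 and CEBPD stand. All 20 measured genes of a list written afterwards, 14 of them lower, gave a camera p of 0.000137 (0.0207 with an estimated correlation), but these include the 5 that prompted it. The other 15 gave a camera p of 0.556, and in an exact enumeration 24 of 35 splits gave one as small, with the smallest other at 0.00803. Because the 5 were left out for their p between the real groups, this p and this rank are pushed toward no change, which the bound set for them did not allow for. Neither value decides, and the hypothesis stays open.

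The spread between replicate arrays was a median SD of 0.38 on the log2 scale, 4.83 times the standard error between beads. The SD was taken after neqc and the bead error on intensities before background correction, so this ratio is only rough. Deviations of 2 probes of a gene correlated by r = 0.148 across 125 genes, where random pairs reached at most 0.113, and genes are not independent replicates. This lies between the bounds set for noise of beads and hybridization, so how much of the spread arose before hybridization cannot be told apart.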
